A study of Mus musculus with 52 samples.

How the data were processed

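Small RNA was sequenced from hippocampal tissue of mice of the strain C57B/6JRj, 20 weeks of age per the labels. Per the labels' protocols, the CA and DG subregions were separated under a microscope and frozen, RNA was extracted with Tri reagent and treated with DNase, and libraries were made with Illumina TruSeq chemistry. Each library belongs to 1 of 8 groups that combine the region (CA, the cornu ammonis, or DG, the dentate gyrus), the housing (home cage, HC, or environmental enrichment, EE) and the time in that housing (2 or 10 weeks). Groups are named accordingly, so that 2wEE_DG holds the dentate gyrus libraries after 2 weeks of enrichment. The groups and library numbers were taken from the sample titles. The labels do not say whether each library came from its own animal, or whether a CA and a DG library with the same number came from the same one. The p-values measure the spread between these samples, which may in part be technical.

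The deposited values are raw read counts per mature miRNA, 1900 in each of 52 libraries. Per the submitters' processing notes, the authors used CASAVA 1.8.2, cutadapt, STAR and HTSeq with the mm10 mouse genome; the versions of the last 3 and the miRNA annotation are not given in the sources used here. The deposited counts end with 5 totals of reads given to no miRNA, which were left out of library sizes and tests. Reads aligned to several places made up 59.3 to 71.0% of the reads in the deposited counts (median 62.5%) and entered no miRNA count. The deposited total of unaligned reads was 0 in every library, so shares of reads here and below leave out any unaligned reads. The sources used here do not say whether a read aligned to several places was counted once. Reads outside any miRNA made up 3.37 to 6.34% and ambiguous reads 0.185 to 0.527%. A mature miRNA made from several hairpins can lose the reads that align to several places, to an extent that the deposited counts do not show. Among miRNAs matched by name to 2 annotated hairpins, miR-124-3p has 57 counts over all libraries and miR-128-3p has 2853444. Ranks by abundance are therefore ranks among reads aligned to 1 place, and the 77 miRNAs matched to more than 1 hairpin can stand too low in them. The lists of miRNAs tested below are affected too. In the neuron-enriched list, which holds both miRNAs above, miR-9-5p has 1746 counts. In the let-7 family, let-7a-5p has 5818 and let-7f-5p 286837. In the synaptic plasticity list, miR-26a-5p has 2169 and miR-92a-3p 789248. Tests of these lists can therefore rest on their other members and on arms from 1 hairpin.

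Hairpins were matched by name in the GENCODE annotation of the same genome build, so that a copy with another name can be missed. This gave coordinates for 1891 of the 1900 miRNAs, 1814 of them with a single hairpin. Total miRNA counts per library ranged from 480792 to 6706855, so that a floor of 3 counts corresponds to 0.447 to 6.24 CPM (counts scaled to library size). Intervals and floors of this kind cover counting error only, as reads carried no molecular identifiers in the deposited counts. Of the 147 pairs of libraries within a group, 0 held identical values. In all of them counts differed by more than sampling noise, with a chi-square per degree of freedom of at least 13.0.

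Differential abundance was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group) in R 4.3.3. CA contrasts were fitted on the 27 CA libraries, DG contrasts on the 25 DG libraries, and contrasts across regions on all 52, each with 1 mean per group and no covariate. All adjusted p-values of single miRNAs are from this edgeR test, two-sided, with Benjamini-Hochberg adjustment over the miRNAs of a contrast, unless another tool is named. The threshold was 0.05. The standard error (SE) of a log2 fold change was taken from the fold change and the F statistic. CPM are TMM-normalized. There were 11 contrasts: enrichment against home cage at each time in each region (4), the difference of that effect between times (2) and between regions (2), DG against CA over all groups, and 10-week against 2-week home cage in each region (2).

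The 14 lists of miRNAs comprised 6 of pathways, families or genomic clusters: the miR-132/miR-212 cluster, the Dlk1-Dio3 imprinted cluster, the let-7 family, neuron-enriched miRNAs, synaptic plasticity miRNAs, and the proliferation clusters (miR-17~92 and its paralogs). The other 8 held markers of oligodendrocytes, astroglia, microglia and leukocytes, erythrocytes, vascular and mesenchymal cells, choroid plexus and ependyma, hindbrain (Hox clusters), and sensory and pineal cells (miR-183 cluster). Lists with at least 3 tested miRNAs were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 135 tests of lists and contrasts. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move, on balance, in 1 direction, and does not compare them with other miRNAs. For each list, single miRNAs were also adjusted over the list alone. In the 19 tests of lists that passed with the preset correlation, the median, the mean and the direction of the test had 1 sign, which was not so in every other test.

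Groups, contrasts, tests, lists and the rule for naming miRNAs were set before the data were examined. For each enrichment contrast the rule names every tested arm of miR-132 and miR-212, the 10 higher and 10 lower called miRNAs with the smallest adjusted p, filled to 5 per direction with the smallest p, and as examples of a list its most abundant or, where members passed, its called members. For DG against CA it names the 10 largest and 10 smallest fold changes among called miRNAs of at least median abundance, and for the other contrasts the 5 miRNAs per direction with the smallest p. Not all of them are printed. The 10 most abundant miRNAs were also set to be named. miRNAs outside the rule are said to have been chosen after their values were seen.

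Alternatives set in advance were DESeq2 1.42.0, limma voom with sample quality weights, RLE and upper-quartile scaling, no filter on low counts, a filter at a mean of 10 CPM, library size as a covariate, fits on only the groups of a contrast, the library number as a block, and leaving out each library in turn. 2 kinds were added after seeing the data: an offset for the trend of each library on the GC content of the hairpin arms, and fits without library 3 of 10wEE_CA. That library had the fewest counts and stood far from all other CA libraries. All libraries were kept in the values reported first, and values without it are given beside them.

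The test was run on counts simulated from the means, library sizes and spread of the real libraries, with 200 miRNAs changed by known folds. For enrichment at 2 weeks in CA (581 miRNAs) it recovered 46.3% of changes of 1.25-fold, 70.1% of 1.5-fold and 93.9% of 2-fold. For enrichment at 2 weeks in DG (525 miRNAs) these shares were 28.4%, 67.2% and 87.9%. For the difference between regions at 2 weeks (593 miRNAs) they were 11.9%, 35.8% and 74.2%. With 200 miRNAs changed at once, the adjustment of p-values is more lenient than where few change. These shares can therefore be too high for contrasts with few calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.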

Results

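Small RNA profiles were compared between enriched and home cage mice in 2 hippocampal subregions. The CA region holds the pyramidal cell fields, and the dentate gyrus (DG) holds the granule cells and a niche of adult neurogenesis. Environmental enrichment is housing with more space, objects and stimulation than a home cage, and the series sets each enriched group against its own home cage control. In CA there were 6 libraries of 2wHC_CA, 7 of 2wEE_CA, 6 of 10wHC_CA and 8 of 10wEE_CA. In DG there were 6 of 2wHC_DG, 5 of 2wEE_DG, 6 of 10wHC_DG and 8 of 10wEE_DG.

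CA libraries held 480792 to 6706855 miRNA counts (median 4189269) and DG libraries 1117213 to 3159957 (median 2093319). The lowest total was that of library 3 of 10wEE_CA. The other 7 libraries of that group held 3242842 counts or more. On the first principal component of the CA libraries, which carried 65.8% of the variance, this library lay at 45.5 and the other 26 between -2.81 and 0.338.

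**Figure D1:**
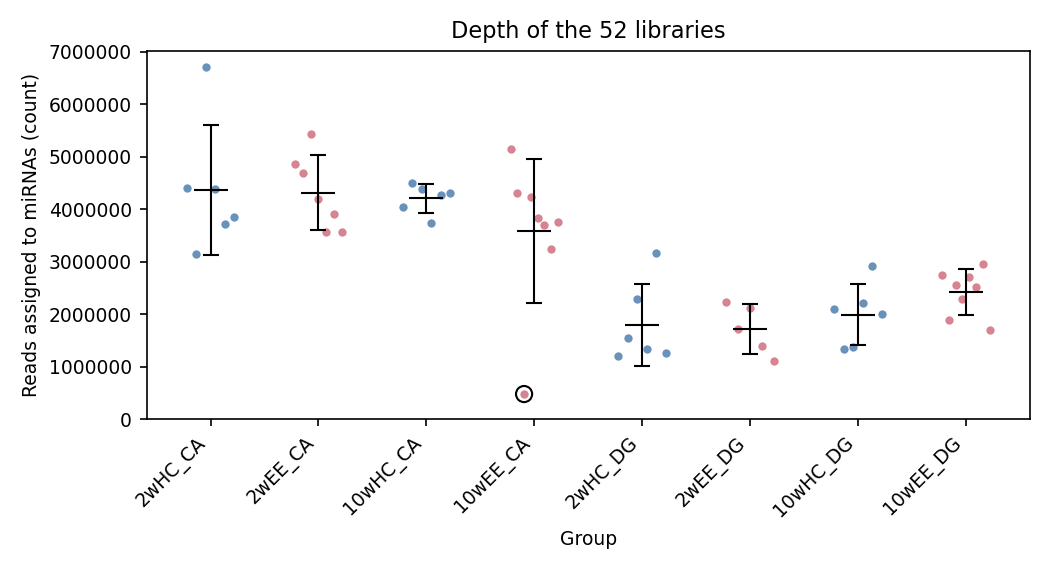
Number of reads assigned to miRNAs (vertical axis) for each of the 52 libraries, by group; points are libraries (blue home cage, red enriched) and bars are the group mean and SD. The circled library, library 3 of 10wEE_CA, holds 480792 counts, fewer than every other library.

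Among reads aligned to 1 place, the most abundant miRNA was miR-127-3p, from the imprinted Dlk1-Dio3 cluster on chromosome 12, with 171646 ± 47082 CPM (SD, n = 52). It was followed by miR-22-3p (89577 ± 9575 CPM), miR-125a-5p (53552 ± 12749 CPM) and miR-434-3p (49773 ± 9043 CPM), which lies in the same cluster as miR-127. The next 6 were miR-30a-5p, miR-27b-3p, miR-92b-3p, miR-191-5p, miR-29a-3p and miR-99b-5p, with means from 48060 down to 23740 CPM. These means are over both regions, and the order differed between them: miR-434-3p had 56322 CPM in CA and 42700 CPM in DG, and miR-125a-5p 43483 CPM in CA and 64426 CPM in DG.

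The first question was what 2 weeks of enrichment changed in the dentate gyrus. miR-132 and miR-212, which are made from 1 primary transcript that neuronal activity and CREB induce, were higher in the enriched libraries. miR-132-3p rose from 3086 ± 305 CPM (SD, n = 6) to 4518 ± 895 CPM (SD, n = 5), a log2 fold change of 0.56 ± 0.10 (SE, adjusted p = 0.00368). miR-132-5p rose by 0.55 ± 0.10 (adjusted p = 0.00278) and miR-212-3p by 0.63 ± 0.13 (adjusted p = 0.00492). The remaining arm, miR-212-5p, had a log2 fold change of 0.34 ± 0.10 (adjusted p = 0.297). All 5 enriched libraries lay above the home cage mean for each of the 4 arms, and all 5 lay above every home cage library for miR-132-5p. Both hairpins lie on the plus strand of chromosome 11 (mm10), Mir212 at 75173388 to 75173478 and Mir132 at 75173682 to 75173747, in an intron of the noncoding transcript 1700016P03Rik.

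These 3 arms were the only miRNAs of 525 to pass in this contrast with edgeR, and 29 had an unadjusted p under 0.05. Adjusted over the list alone, all 4 arms of the miR-132/miR-212 cluster were higher. The cluster was higher as a list in camera (adjusted p = 9.41e-12), and remained so with an estimated correlation (adjusted p = 0.0118 with an estimated correlation) and in fry (adjusted p = 0.000102). Of the 28 tested synaptic plasticity miRNAs, 2 were higher, both arms of miR-132; adjusted over the list alone 2 were higher and 1 lower. No member of the other lists passed over all miRNAs. The Dlk1-Dio3 cluster, with 82 tested members, had a median log2 fold change of 0.04 and a camera adjusted p of 0.073. The marker lists gave camera adjusted p-values of 0.549 for vascular and mesenchymal cells, 0.698 for astroglia, 0.812 for oligodendrocytes, 0.816 for erythrocytes, 0.816 for choroid plexus and ependyma, and 0.888 for microglia and leukocytes. The choroid plexus and ependyma list had a median of -0.08 and a mean of 0.02. Among miRNAs that did not pass, miR-125a-5p had the smallest p of those lower in enriched libraries, with a log2 fold change of -0.36 ± 0.09 (adjusted p = 0.0548), and DESeq2 called it (adjusted p = 0.0163). miR-125b-5p had -0.27 ± 0.10, miR-652-3p -0.29 ± 0.10 and miR-22-3p 0.23 ± 0.08 (adjusted p = 0.506 for each). In 10wHC_DG against 2wHC_DG, miR-125a-5p and miR-125b-5p had log2 fold changes of -0.29 and -0.33 (adjusted p = 0.022 and 0.0197). Between the enriched groups of these times they had 0.07 and 0.03. For these 2 miRNAs a shift of the home cage group can therefore not be told apart from an effect of enrichment. In a fit of only these 2 groups, miR-132-3p and miR-212-3p had adjusted p-values of 0.0772 and 0.0983, the highest of their 10 alternatives (lowest 8.96e-05 and 0.000209), and without library 5 of 2wEE_DG miR-212-3p had 0.0505.

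**Figure D2:**
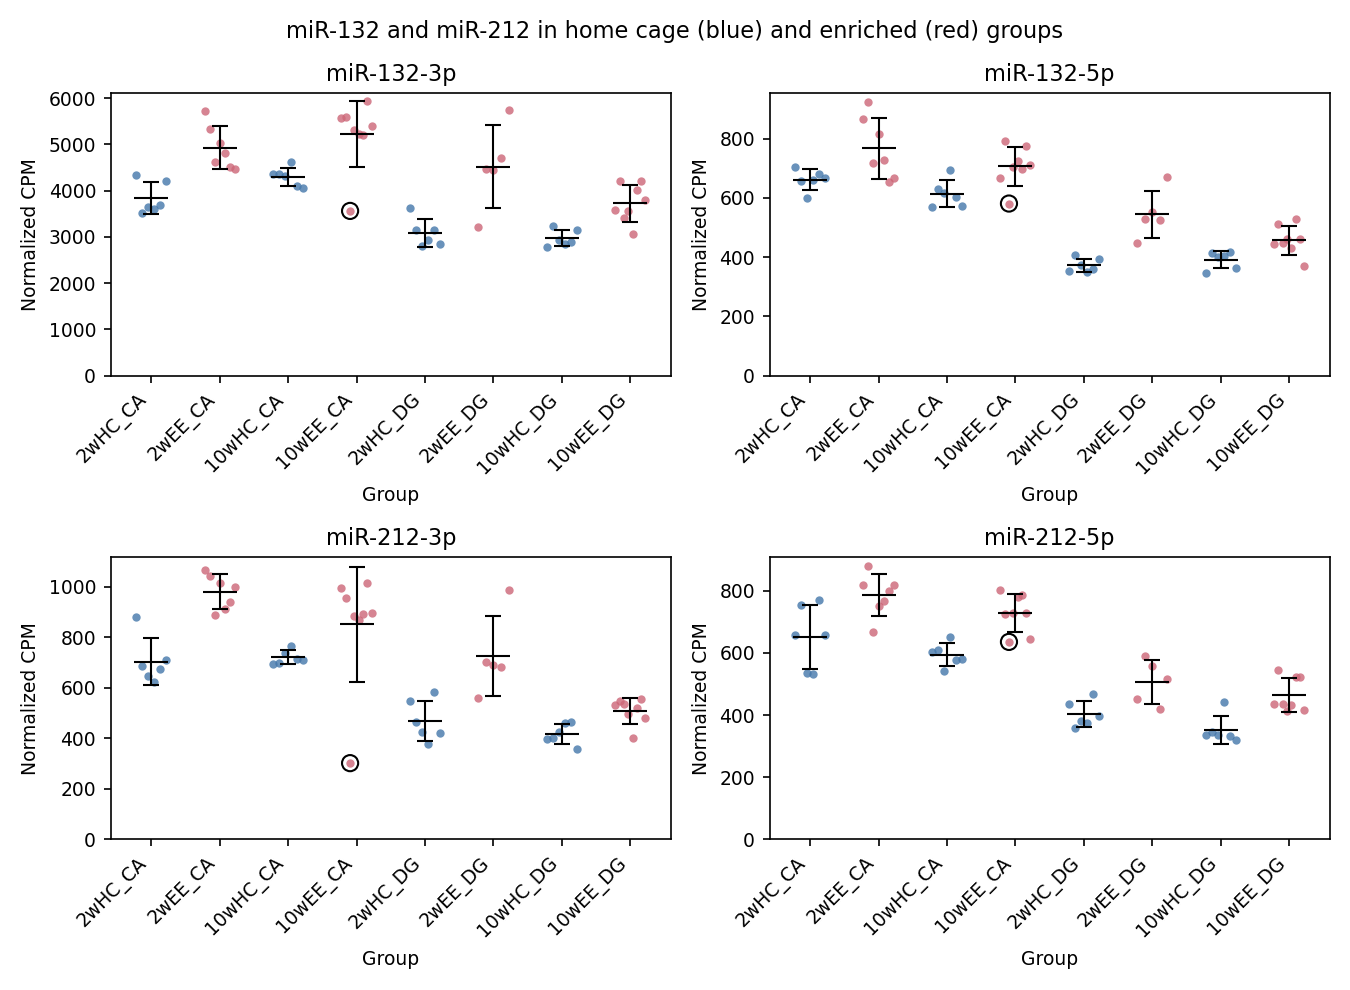
Normalized abundance in CPM (vertical axes) of the 4 arms of miR-132 and miR-212 in each library, by group; points are libraries (blue home cage, red enriched), bars are the group mean and SD, and the circled point is library 3 of 10wEE_CA. Enriched groups have the higher mean in each region and at each time, with miR-132-5p in DG at 2 weeks at 372 CPM in home cage and 545 CPM in enriched libraries.

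After 10 weeks of enrichment in the dentate gyrus, miR-212-5p was the arm of the cluster that passed. It rose from 352 ± 44.7 CPM (SD, n = 6) to 466 ± 54.7 CPM (SD, n = 8), a log2 fold change of 0.40 ± 0.09 (adjusted p = 0.0421). For this arm 8 of 8 enriched libraries lay above the home cage mean, and 3 of 8 above every home cage library. The log2 fold changes of miR-132-3p (0.33 ± 0.09, adjusted p = 0.308), miR-132-5p (0.22 ± 0.09, adjusted p = 0.709) and miR-212-3p (0.29 ± 0.11, adjusted p = 0.709) did not pass. miR-5100, from an intron of Mief2 on chromosome 11, fell by 1.78 ± 0.37 on the log2 scale (adjusted p = 0.0241), from 17.2 ± 9.44 CPM to 4.60 ± 3.69 CPM. It is a rare miRNA, with a median count of 33 in home cage and 10.5 in enriched libraries. miR-5100 was also higher in 10wHC_DG than in 2wHC_DG, by 3.17 on the log2 scale. A shift of the home cage group can therefore not be told apart from an effect of enrichment.

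Of 525 miRNAs, these 2 passed with edgeR and 29 had an unadjusted p under 0.05. Oligodendrocyte miRNAs had 1 of 5 lower adjusted over the list alone. All 4 arms of the miR-132/miR-212 cluster were higher adjusted over the list alone; camera gave the list an adjusted p of 1.89e-06, which was lost (adjusted p = 0.0702 with an estimated correlation), and fry gave 0.00644. Erythrocyte miRNAs had a higher median (0.35) with all 5 tested members positive, among them miR-451a at 0.35 ± 0.21 and miR-144-5p at 0.40 ± 0.18. This list passed in camera (adjusted p = 0.000138), but not with an estimated correlation (adjusted p = 0.178 with an estimated correlation), and 1 member was higher adjusted over the list alone. The let-7 family, which restrains proliferation in many tissues, had a median of -0.12 with 2 of 18 members positive (camera adjusted p = 0.00524; adjusted p = 0.653 with an estimated correlation). let-7g-5p had -0.23 ± 0.08 and let-7b-5p -0.22 ± 0.09, and 0 of the 18 members passed in edgeR, over all miRNAs or adjusted over the list alone. In 10wHC_DG against 2wHC_DG, let-7g-5p and let-7b-5p were higher by 0.26 and 0.38 on the log2 scale. Neuron-enriched miRNAs had a median of -0.11 with 3 of 21 positive (camera adjusted p = 0.0315; adjusted p = 0.258 with an estimated correlation), and 0 passed. miR-34c-5p and miR-34b-5p, which are abundant in ciliated cells, had 0.56 ± 0.18 and 0.50 ± 0.19 (adjusted p = 0.343 and 0.709). The choroid plexus and ependyma list had a camera adjusted p of 0.0786, astroglia 0.561, microglia and leukocytes 0.783, oligodendrocytes 0.404, and vascular and mesenchymal cells 0.301. The mean share of reads assigned to miRNAs was 26.7% in the home cage libraries of this contrast and 29.9% in the enriched ones. Both calls of single miRNAs are fragile: voom, a filter at a mean of 10 CPM, and the 2-group fit each left 0, and so did leaving out library 2 or 5 of 10wHC_DG or library 3, 6 or 7 of 10wEE_DG. miR-212-5p was the weaker call, and passed in 2 of its 10 alternatives and in 2 of 14 fits that left out a library. miR-5100 passed in 6 of 9 and in 9 of 14.

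In CA after 2 weeks of enrichment, the same cluster led the contrast. miR-132-3p had 3834 ± 346 CPM (SD, n = 6) in home cage and 4924 ± 464 CPM (SD, n = 7) in enriched libraries, a log2 fold change of 0.34 ± 0.08 (adjusted p = 0.15), and 7 of 7 enriched libraries lay above every home cage library. For miR-212-3p the values were 703 ± 91.7 CPM and 980 ± 68.0 CPM, a log2 fold change of 0.46 ± 0.14 (adjusted p = 0.422), again with 7 of 7 above every home cage library. miR-212-5p had 0.25 ± 0.09 and miR-132-5p 0.20 ± 0.08. As a list, the miR-132/miR-212 cluster was higher (camera adjusted p = 1.34e-08; adjusted p = 0.0188 with an estimated correlation; fry adjusted p = 0.00474), and 4 of 4 arms were higher adjusted over the list alone.

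With all libraries, 0 of 581 miRNAs passed with edgeR, 35 had an unadjusted p under 0.05, DESeq2 called 1 (miR-132-3p) and voom called 8. The spread of the CA fit depended on library 3 of 10wEE_CA, a group that does not enter this contrast. Without that library, edgeR called 9 miRNAs. The 7 higher ones were miR-212-3p (0.45 ± 0.06, adjusted p = 5.65e-05; highest of its alternatives 0.924), miR-132-3p (0.33 ± 0.06, adjusted p = 0.00132; highest 0.924), miR-21a-5p (0.25, adjusted p = 0.00165), miR-381-3p (0.22), miR-27b-3p (0.21), miR-582-3p (0.26) and miR-192-5p (0.18). miR-21a is enriched in glia, and miR-381 belongs to the Dlk1-Dio3 cluster. The 2 lower ones were both arms of miR-187, miR-187-3p (-0.43, adjusted p = 0.0162) and miR-187-5p (-0.57, adjusted p = 0.027). miR-187-3p, which was named after its values were seen, as were miR-21a-5p and miR-381-3p among these calls, stood at 231 ± 31.5 CPM in 2wHC_CA and 174 ± 20.4 CPM in 2wEE_CA.

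Neuron-enriched miRNAs had a median of -0.08 in this contrast with 6 of 21 positive (camera adjusted p = 0.0425; adjusted p = 0.258 with an estimated correlation; 0.0578 without library 3 of 10wEE_CA, with 3 of 21 positive), and 0 passed in edgeR. Of these, miR-128-3p, which is made from 2 hairpins, had -0.21 ± 0.08 (adjusted p = 0.468). No marker list passed: camera adjusted p-values were 0.204 for microglia and leukocytes, 0.329 for oligodendrocytes, 0.337 for erythrocytes, 0.819 for choroid plexus and ependyma, 0.819 for vascular and mesenchymal cells and 0.963 for astroglia. miR-34c-5p and miR-34b-5p had log2 fold changes of 0.53 ± 0.19 and 0.57 ± 0.20 (adjusted p = 0.468 for each), and both passed in a fit of only these 2 groups.

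In CA after 10 weeks of enrichment, miR-132-3p had 4297 ± 201 CPM (SD, n = 6) in home cage and 5222 ± 713 CPM (SD, n = 8) in enriched libraries, a log2 fold change of 0.28 ± 0.08 (adjusted p = 0.572). 7 of the 8 enriched libraries lay above every home cage library, and library 3 lay below every one, at 3561 CPM. miR-212-5p had 0.30 ± 0.09, miR-132-5p 0.21 ± 0.08 and miR-212-3p 0.24 ± 0.14 (adjusted p = 0.572, 0.82 and 0.848). Adjusted over the list alone, 3 of the 4 arms were higher. The list passed in camera (adjusted p = 0.000119), was lost (adjusted p = 0.146 with an estimated correlation), and had a fry adjusted p of 0.0637.

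With all libraries, 0 of 581 miRNAs passed with edgeR, 30 had an unadjusted p under 0.05, DESeq2 called 0 and voom called 5. Without library 3, edgeR called 3: miR-132-3p (0.34 ± 0.06, adjusted p = 0.00126), miR-212-3p (0.36 ± 0.06, adjusted p = 0.00126) and miR-148a-3p, which fell by 0.34 ± 0.08 on the log2 scale (adjusted p = 0.0263) and was named after its values were seen. miR-148a-3p stood at 5098 ± 241 CPM (SD, n = 6) in home cage and 4064 ± 306 CPM (SD, n = 7) in enriched libraries without library 3. The miR-132/miR-212 list without that library passed with an estimated correlation (adjusted p = 0.0139 with an estimated correlation). The let-7 family had a median of 0.22 with 16 of 19 positive and passed in camera (adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.622 with an estimated correlation) and not without library 3 (median 0.03, 12 of 19 positive, adjusted p = 0.761). In library 3 the family lay 1.09 above the other libraries of its group. Erythrocyte miRNAs had a median of 0.38 (camera adjusted p = 0.202), with miR-451a at 0.53 ± 0.19 (adjusted p = 0.82). Without library 3 the erythrocyte list passed in camera with 6 of 6 members positive and a median of 0.24 (adjusted p = 0.0103; adjusted p = 0.225 with an estimated correlation), and miR-451a had 0.30 ± 0.11. The other marker lists gave camera adjusted p-values of 0.131 for choroid plexus and ependyma, 0.517 for oligodendrocytes, 0.656 for astroglia, 0.656 for microglia and leukocytes, and 0.819 for vascular and mesenchymal cells. miR-10a-5p and miR-10b-5p, of the hindbrain list, had log2 fold changes of 0.16 ± 0.18 and 0.06 ± 0.43 here, and of 0.06 ± 0.16 and -0.15 ± 0.40 without library 3.

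Whether the effect of enrichment differed between 10 and 2 weeks was tested within each region. In DG, miR-132-5p had a difference of -0.33 ± 0.13 (adjusted p = 0.993), miR-125a-5p 0.37 ± 0.12 and miR-486-5p, an erythroid miRNA, 0.84 ± 0.27 (adjusted p = 0.846 for both). For miR-125a-5p, the log2 fold change from 2 to 10 weeks was -0.29 in home cage and 0.07 in enriched DG libraries. In CA, miR-451a had 0.67 ± 0.26, miR-494-3p 0.62 ± 0.23 and miR-7688-5p -0.63 ± 0.18 (adjusted p = 0.994 for each). With edgeR 0 miRNAs passed in either region, with 21 in DG and 13 in CA at an unadjusted p under 0.05, and DESeq2 and voom called 0. As lists in DG, erythrocyte miRNAs had a positive difference (median 0.36, camera adjusted p = 0.00353; adjusted p = 0.28 with an estimated correlation), and the miR-132/miR-212 cluster (median -0.28, adjusted p = 0.0498; adjusted p = 0.608 with an estimated correlation) and the let-7 family (median -0.20, adjusted p = 0.0114; adjusted p = 0.664 with an estimated correlation) negative ones. In CA, erythrocyte miRNAs had a median difference of 0.50 (camera adjusted p = 0.0498; adjusted p = 0.208 with an estimated correlation). Without library 3 of 10wEE_CA the list had a median of 0.40 (camera adjusted p = 0.000267; adjusted p = 0.0523 with an estimated correlation), 3 members were higher adjusted over the list alone against 0 with all libraries, and miR-451a had 0.45 ± 0.15.

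Whether the effect differed between regions was tested over all 52 libraries. At 2 weeks, the 4 arms of miR-132 and miR-212 had a median difference, DG minus CA, of 0.17, with miR-132-5p at 0.33 ± 0.13 (adjusted p = 0.999). The list passed in camera (adjusted p = 0.0162), but not with an estimated correlation (adjusted p = 0.499 with an estimated correlation), and 1 arm was higher adjusted over the list alone. At 10 weeks, the let-7 family had a median difference of -0.30 with 2 of 19 positive, and let-7d-5p and let-7g-5p had -0.50 ± 0.17 each (adjusted p = 0.787 for both). The family passed in camera (adjusted p = 4.17e-06), but not with an estimated correlation (adjusted p = 0.258 with an estimated correlation), and 4 members were lower adjusted over the list alone. Without library 3 of 10wEE_CA the family had a median of -0.17 with 6 of 19 positive (camera adjusted p = 0.00121; adjusted p = 0.516 with an estimated correlation), none of its members was lower adjusted over the list alone, and let-7d-5p and let-7g-5p had -0.33 ± 0.14 and -0.24 ± 0.10. Also without that library, the Dlk1-Dio3 cluster passed at 2 weeks (camera adjusted p = 0.0153; adjusted p = 0.778 with an estimated correlation) and vascular and mesenchymal miRNAs at 10 weeks (camera adjusted p = 0.00594; adjusted p = 0.606 with an estimated correlation). With edgeR 0 of 593 miRNAs passed at either time, with 17 at 2 weeks and 25 at 10 weeks at an unadjusted p under 0.05, and DESeq2 and voom called 0.

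The 2 regions themselves differed in most miRNAs. In DG, miR-184-3p was higher at 111 ± 24.9 CPM (SD, n = 25) against 11.5 ± 5.26 CPM in CA (SD, n = 27), a log2 fold change of 3.28 ± 0.13 (adjusted p = 1.16e-28). miR-187-3p was higher by 2.59 ± 0.09, with 1181 ± 197 CPM against 193 ± 45.5 CPM. miR-344d-3-5p (1.83 ± 0.06), miR-222-3p (1.63 ± 0.08), miR-504-5p (1.55 ± 0.07), miR-3099-3p (1.54 ± 0.08), miR-204-5p (1.41 ± 0.08), miR-672-5p (1.37 ± 0.07), miR-760-3p (1.32 ± 0.08) and miR-342-5p (1.28 ± 0.09) followed. miR-204, from an intron of Trpm3, is also abundant in choroid plexus.

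Among the miRNAs lower in DG, miR-200b-3p and miR-429-3p, members of the epithelial miR-200 family on chromosome 4, had log2 fold changes of -4.04 ± 0.26 and -4.04 ± 0.24. miR-429-3p stood at 175 ± 71.0 CPM in CA and 10.5 ± 10.2 CPM in DG. The p53-linked miR-34 family was lower in DG at both of its loci, with miR-34c-5p at -2.41 ± 0.10, miR-34b-5p at -2.48 ± 0.11 and miR-34a-5p at -2.36 ± 0.09. miR-34c-5p was the most abundant of these, with 5431 ± 1584 CPM in CA and 1031 ± 330 CPM in DG. 3 arms from introns of Htr2c, a serotonin receptor gene, were also lower in DG: miR-1298-3p (-2.34 ± 0.11), miR-448-3p (-2.29 ± 0.23) and miR-1298-5p (-2.21 ± 0.23). miR-490-3p, from an intron of the muscarinic receptor gene Chrm2, had -2.25 ± 0.10.

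**Figure D3:**
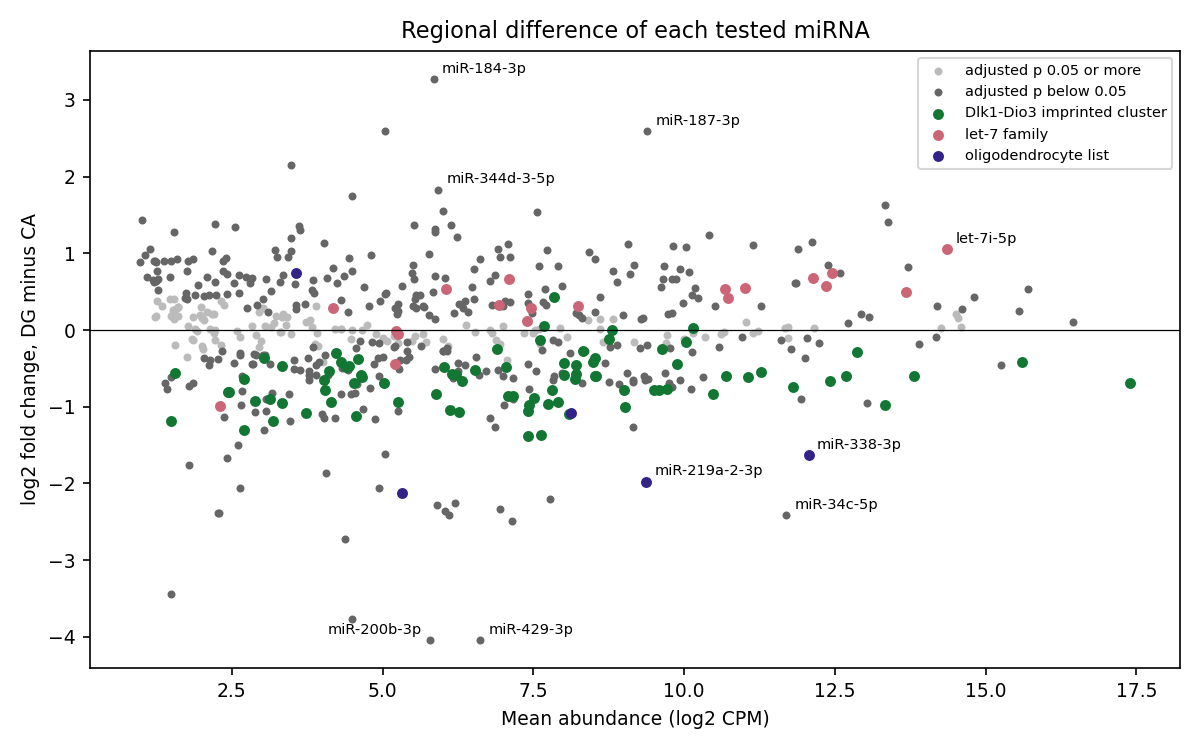
Log2 fold change of each of the 593 tested miRNAs between DG and CA (vertical axis) against its mean abundance in log2 CPM (horizontal axis); grey shades give the side of the edgeR threshold and colours mark 3 lists. Most of the Dlk1-Dio3 cluster lies below 0, with a median of -0.64, while let-7 family members lie mostly above it.

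Of 593 miRNAs, 461 passed between regions with edgeR, 214 higher and 247 lower in DG. Of the 85 tested members of the Dlk1-Dio3 imprinted cluster, rich in brain miRNAs, 79 were lower and 1 higher, over all miRNAs and adjusted over the list alone. miR-496a-3p had -1.39 ± 0.07, miR-758-3p -1.05 ± 0.06, miR-377-5p -0.94 ± 0.05 and miR-300-3p -0.66 ± 0.04. The cluster was lower in camera (adjusted p = 1.91e-12), which was lost (adjusted p = 0.066 with an estimated correlation), and its fry adjusted p was 2.02e-20. In the let-7 family 14 of 19 members were higher and 2 lower, with let-7i-5p at 1.05 ± 0.06 and let-7b-5p at 0.74 ± 0.04 (camera adjusted p = 0.0156; adjusted p = 0.622 with an estimated correlation).

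All 4 arms of miR-132 and miR-212 were lower in DG, from -0.36 ± 0.05 for miR-132-3p to -0.68 ± 0.05 for miR-212-5p (camera adjusted p = 0.0613). Of the 21 neuron-enriched miRNAs, 12 were higher and 5 lower (camera adjusted p = 0.202), with miR-137-5p at 1.04 ± 0.09 and miR-129-1-3p at -1.26 ± 0.07. Synaptic plasticity miRNAs went both ways, with 8 of 29 higher and 14 lower (camera adjusted p = 0.969), and so did the proliferation clusters, with 7 of 15 higher and 6 lower (camera adjusted p = 0.755). Adjusted over the list alone, these 3 counts were the same. Reads aligned to several places do not enter these lists, so members made from several hairpins may count little in them.

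Markers of other cell types were compared in the same way, where 461 of 593 miRNAs passed in all. A marker that passed is therefore not by itself a sign of a different share of its cell type. Of the 5 oligodendrocyte miRNAs, 4 were lower in DG and 1 higher, with miR-338-3p at -1.63 ± 0.05 and miR-219a-2-3p at -1.97 ± 0.07 (camera adjusted p = 0.0315; adjusted p = 0.262 with an estimated correlation; 0.0642 in camera without library 3 of 10wEE_CA). Of the 11 astroglia-enriched miRNAs 7 were lower, miR-21a-5p at -0.90 ± 0.06 among them, and 0 higher, or 7 lower and 2 higher without library 3 of 10wEE_CA (camera adjusted p = 0.136 with all libraries). Of the 12 choroid plexus and ependyma miRNAs 7 were lower and 4 higher (camera adjusted p = 0.202), and of 6 erythrocyte miRNAs 4 were lower (camera adjusted p = 0.535). Microglia and leukocyte miRNAs had 2 of 7 lower and 0 higher (camera adjusted p = 0.882), or 2 lower and 2 higher without that library. Of this list, miR-142-5p had -0.20 ± 0.07, -0.095 ± 0.034 without library 3 of 10wEE_CA and 0.044 with the offset for GC content. Vascular and mesenchymal miRNAs had 2 of 9 higher and 1 lower (camera adjusted p = 0.969), and of the 3 sensory and pineal miRNAs none passed, with miR-182-5p at -0.39 ± 0.21 (camera adjusted p = 0.861). Of the hindbrain list, miR-10b-5p was higher in DG by 0.95 ± 0.33 (adjusted p = 0.0079). Without library 3 of 10wEE_CA, 472 miRNAs passed, 449 of them shared with the fit of all libraries.

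The home cage groups of 2 and 10 weeks came from mice of 1 age in the labels and served as a background comparison. In DG, miR-221-3p, from a cluster shared with miR-222, was higher in 10wHC_DG than in 2wHC_DG by 0.81 ± 0.10 (adjusted p = 2.94e-06), miR-598-3p by 0.99 ± 0.13 and miR-338-5p by 1.17 ± 0.20. miR-5100 was higher by 3.17 ± 0.51, and miR-3102-3p by 1.04 ± 0.17. miR-92b-3p fell by 0.71 ± 0.09 (adjusted p = 7.1e-06), miR-674-3p by 0.64 ± 0.11, miR-1249-3p by 0.62 ± 0.12, miR-501-3p by 0.55 ± 0.11 and miR-298-5p by 1.06 ± 0.22.

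In DG 84 of 525 miRNAs passed with edgeR, 40 higher and 44 lower. The count fell to 51 with no filter on low counts, and to 48, 53 and 51 without library 4 or 1 of 2wHC_DG or library 5 of 10wHC_DG; a fit of only these groups gave 55. Upper-quartile scaling, which moved the median of all miRNAs by 0.14 here, by -0.11 in the duration difference in DG and by 0.11 between regions, gave 74 higher and 16 lower. Astroglia-enriched miRNAs had 3 of 11 higher, and passed in camera (adjusted p = 0.0432; adjusted p = 0.622 with an estimated correlation). The let-7 family had 5 of 18 higher (camera adjusted p = 0.202), neuron-enriched miRNAs 5 of 21 higher (0.136), synaptic plasticity miRNAs 3 higher and 3 lower of 28 (0.656), and the Dlk1-Dio3 cluster 3 higher and 6 lower of 82 (0.952). In CA, with edgeR, 0 of 581 miRNAs passed between the home cage groups and 35 had an unadjusted p under 0.05; DESeq2 called 3 and voom 11, and edgeR without library 3 of 10wEE_CA called 12. The smallest p-values in CA were those of miR-24-1-5p (-0.54 ± 0.13) and miR-3086-5p (0.49 ± 0.12), with an adjusted p of 0.115 for both.

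The share of reads outside miRNAs also followed the time in housing. In DG these were 3.81 to 4.45% of reads in the 11 libraries of 2 weeks and 4.88 to 6.34% in the 14 libraries of 10 weeks, and in CA 3.37 to 3.96% in 13 libraries and 4.28 to 4.78% in 14. The 2-week and 10-week libraries therefore did not overlap in this share in either region, and the home cage comparisons across times cannot be separated from it. Contrasts of enriched with home cage libraries were made within 1 time. In DG at 10 weeks, assigned reads were 26.7 ± 2.62% in home cage (SD, n = 6) and 29.9 ± 1.88% in enriched libraries (SD, n = 8), reads aligned to several places 67.3 ± 2.35% and 64.6 ± 1.96%, and reads outside miRNAs 5.70 ± 0.502% and 5.22 ± 0.256%.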

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

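The tests chosen only after the result was seen are the GC trend as a part of the deviation of 1 library, the spread of neuron-enriched miRNAs in it, the GC offset for the 84 home cage miRNAs, the share of dentate tissue for miR-187, and all counts of other splits. A sample counted as far from its group when its gap to the next sample passed Dixon's 95% value. This held in 14 of 104 tests of a measure within a group, and chance gives about 1 in 20, or 5.2. Of the 14, 9 were values of library 3 of 10wEE_CA, and the 5 of other libraries are about as many as chance gives. The measures included miR-148a-3p, miR-21a-5p and both arms of miR-187, which edgeR called in fits without library 3. Their values are among the 9, and this choice may have favoured them, so the number given by chance is only a rough guide.

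Library 3 of 10wEE_CA lay far from the other 7 of its group. It held 480792 miRNA counts (others 3242842 to 5139167), 70.2% of its reads aligned to several places (others 60.7 to 62.9%), and 619 miRNAs had a count (others 897 to 982). Its levels were 3561 CPM for miR-132-3p (others 5199 to 5939), 301 CPM for miR-212-3p (others 870 to 1014), 36.5 CPM for miR-187-3p (others 164 to 202) and 1.83 CPM for miR-187-5p (others 6.73 to 10.8). It had 11055 CPM of miR-21a-5p (others 4772 to 5501) and 6233 CPM of miR-148a-3p (others 3412 to 4263).

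The median absolute log2 deviation of this library from the other libraries of its group was 1.20. Those other libraries, thinned to its depth, reached up to 0.229, which argues against low depth. Its deviation followed the GC content of the hairpin arm over 580 miRNAs (rho -0.713, other libraries -0.237 to 0.234), consistent with a GC trend for part of it, but after that trend was taken off 0.786 remained (others up to 0.159). The microglia and leukocyte list had a median deviation of 1.05 (others -0.333 to 0.229), which other tissue could give, yet the let-7 family, not a marker of these cells, had 1.09. The 145 miRNAs with the lowest arm GC content (up to 44%) had a median of 1.11. The marker list was not compared after the GC trend was taken off, so its value cannot tell other tissue apart from that trend. Deviations of the neuron-enriched miRNAs had an SD of 1.43 (thinned libraries up to 0.660), which argues against dilution by other tissue as the whole cause. No biological explanation was tested for this single library.

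The 84 miRNAs called between the DG home cage groups may follow a batch or cohort that goes with the time in housing. Of them, 95.2% had the same sign between the enriched DG groups, which an effect of the time would give as well. The shares of reads outside miRNAs did not overlap between times in DG, nor in CA. Between the CA home cage groups, however, 46 of the 84 had the same sign. Their signed median there was 0.01 (SD 0.16), against 0.37 in enriched DG. This argues against a batch that moved these miRNAs alike in both regions. A batch of the DG libraries alone stays open. A different share of CA tissue cannot be told apart, with a rho of -0.328 between these miRNAs and the region difference, nor can a GC trend, since 59 of the 84 remained with the GC offset. An effect of the time in housing stays open, because the batch and the time are confounded. Of 100 splits of the samples, 1, the real one, gave as many calls (84, highest other 15), so chance alone is unlikely to give this count.

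Both arms of miR-187 were lower in enriched CA at 2 weeks in the fit without library 3 of 10wEE_CA, and miR-187-3p is among the miRNAs highest in DG. Less DG tissue in the enriched libraries would lower the other 9 such miRNAs by a predicted median of -0.18. Their median was -0.039 (SD 0.14), and 6 of the 9 were lower. The formula for the predicted value was changed after a first result had been seen. The 2 medians lie only about this SD apart, so less DG tissue cannot be told apart. With the GC offset the higher of the 2 adjusted p-values was 0.0132, which argues against a GC trend as the whole cause. A response of miR-187 to enrichment may explain it and stays a hypothesis.

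Other samples far from their group were library 3 of 2wHC_CA with 6706855 counts (others up to 4407177), library 1 of 2wHC_CA with 880 CPM of miR-212-3p (others 623 to 710), and library 4 of 10wHC_DG with 442 CPM of miR-212-5p (others 320 to 347). Library 2 of 10wEE_CA had 12.4 CPM of miR-5100 (others up to 2.92), and library 6 of 2wHC_DG had 10278 CPM of miR-148a-3p (others 7879 to 8166).

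Differences between times or regions passed in camera with the preset correlation in 6 tests of 3 lists. Between times these were erythrocyte miRNAs in CA (adjusted p = 0.0498) and DG (adjusted p = 0.00353), and in DG the miR-132/miR-212 cluster (adjusted p = 0.0498) and the let-7 family (adjusted p = 0.0114). Between regions they were the miR-132/miR-212 cluster at 2 weeks (adjusted p = 0.0162) and the let-7 family at 10 weeks (adjusted p = 4.17e-06). None of the 6 passed with an estimated correlation. The difference between the home cage groups of 10 and 2 weeks itself differed between DG and CA for 13 miRNAs (42 without library 3 of 10wEE_CA), among them miR-221-3p (0.73) and miR-3086-5p (-0.84).

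For enrichment at 2 weeks in DG, 4 of 100 splits gave as many calls as the real 3. However, 1 other split called 79, which points to a structure of the samples that was not tested. With such a structure the splits cannot decide whether chance gave the 3 calls. At 10 weeks in DG 6 of 100 splits gave as many as the real 2 (highest other 6), so chance cannot be excluded. The real count was 0 in CA at 2 and 10 weeks (highest other 1 in each) and between the CA home cage groups (highest other 0). It was also 0 in the differences between times in CA (highest other 4) and DG (5). The same held for the differences between regions at 2 (highest other 2) and 10 weeks (3). With 0 real calls, 100 of 100 splits gave as many, which was certain in advance and says nothing on chance. Between regions only the real split of 100 reached its 461 calls (highest other 0). Without library 3 of 10wEE_CA, 3 of 100 splits reached the 9 calls of enrichment in CA at 2 weeks (highest other 16). Also without it, 1 reached the 3 calls at 10 weeks (highest other 1), and 1 the 12 calls between home cage groups (highest other 2). The difference between times had 0 calls there, which 100 of 100 splits were certain to reach (highest other 4).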

How the results depend on the processing

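The offset for GC content and the fits without library 3 of 10wEE_CA were chosen after the data were seen. The differences of the enrichment effect between times and between regions had 0 calls under every alternative run (edgeR, DESeq2 and voom, with 13 to 25 at an unadjusted p under 0.05 in edgeR). The comparison of region DG against CA gave 345 to 550 calls. Of 304 named values under 10148 combinations with a setting, 9943 kept their side of the threshold and their direction or lay within 1 SE, 97 came to pass it, 68 no longer passed it and 39 moved. In 211 combinations a value that did not pass changed its sign, in most by no more than 1 SE. 1 value that passed reversed, miR-142-5p in DG against CA, with 0.044 under the GC offset. Except where fewer samples or miRNAs entered the fit, the cause was not tested.

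Enrichment in CA at 2 weeks had 0 calls, and 1 with DESeq2, 3 with library size as covariate, 8 with voom, 2 with the GC offset and 6 with only the groups of the contrast. Without library 3 of 10wEE_CA it had 9, with the block added 3 (miR-132-3p, miR-212-3p and miR-21a-5p) and with the GC offset added 6. At 10 weeks in CA the 0 calls became 1 with library size and 5 with voom, and without that library 2 with the block and 3 with the GC offset. In DG at 2 weeks the 3 calls became 1 with only the groups of the contrast, and 4 with DESeq2, voom, library size, the GC offset and the filter at 10 CPM. At 10 weeks in DG the 2 calls became 1 with RLE scaling, 1 with upper-quartile scaling, 1 with the GC offset, 4 with library size, and 0 with voom, with only the groups of the contrast, with the block, and with the filter at 10 CPM, which removes miR-5100 from the test.

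Between home cage groups in CA the 0 calls became 3 with DESeq2, 2 with no filter, 4 with library size, 11 with voom and 8 with only the groups of the contrast. Without library 3 of 10wEE_CA they became 12, with the block added 8 and with the GC offset added 13. In DG the 84 calls became 51 with no filter (48 shared) and 55 with only the groups of the contrast (54 shared). Of the pathway lists 14 tests passed, and 2 with an estimated correlation (3 without library 3 of 10wEE_CA) and 8 with fry. Of the marker lists 5 passed, and 0 with an estimated correlation, with or without that library, and 4 with fry (1 shared).

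Leaving out each library in turn gave 0 to 3 calls for enrichment at 10 weeks in CA, 3 of them without library 3 of 10wEE_CA. At 10 weeks in DG it gave 0 to 2, with 0 without libraries 2 or 5 of 10wHC_DG or 3, 6 or 7 of 10wEE_DG, and 1 without libraries 1 or 6 of 10wHC_DG or 2, 4 or 5 of 10wEE_DG. Between home cage groups it gave 0 to 2 in CA (2 without library 1 of 2wHC_CA) and 48 to 91 in DG (48 and 53 without libraries 4 and 1 of 2wHC_DG, 51 without library 5 of 10wHC_DG). For DG at 2 weeks it gave 2 to 4, and for DG against CA 446 to 472.

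The library numbers were checked for pairing. Only 2wHC_CA and 2wHC_DG had a correlation above 0.1 in all 6 pairs (mean 0.349, other pairs -0.0712), with 5 of 6 libraries closest to their own number, a hint from the data that these may be pairs. The other 7 comparisons each had negative values. Some of these compared home cage with enriched libraries, which says nothing on pairs of CA and DG, so such pairs are not excluded. Libraries were treated as unpaired throughout, and a test over both regions may therefore count the same animal more than once. With the number as a block, DG had 3 calls at 2 weeks and 85 between home cage groups, and the regions 448, and 11 tests of pathway lists and 4 of marker lists passed in camera. Depth limits the rarest miRNAs, since 3 counts correspond to 6.24 CPM in library 3 of 10wEE_CA.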

Other observations

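The comparison of arms from 2 hairpins, the mean over the 4 enrichment contrasts, the splits of the samples for miR-132 and miR-212 and the test of differences in their size were all chosen after the data were seen. The test of the Dlk1-Dio3 cluster as a set was written before its result.

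Some miRNAs are made from 2 hairpins whose other arms differ in sequence and are counted apart. Of 14 such pairs, 11 had a different ratio of these arms in DG and CA (permutation p = 1e-04, the smallest the permutations can give, adjusted p = 0.000127 for each, two-sided, 26 CA and 25 DG libraries, without library 3 of 10wEE_CA). The log2 ratio of miR-219a-1-3p to miR-219a-2-3p, arms from the hairpins of an oligodendrocyte miRNA, was higher in DG by 2.72, and that of miR-181a-1-3p to miR-181a-2-3p differed by -1.68, with 25 of 25 DG libraries beyond every CA library in both. For miR-218-1-3p and miR-218-2-3p, from introns of the axon guidance genes Slit2 and Slit3, the difference was -0.99. Smaller ones were those of miR-16 (-0.79), miR-138 (0.65), miR-24 (-0.62), let-7f (-0.59), miR-7a (-0.57), miR-129 (-0.52), miR-30c (-0.33) and miR-128 (-0.33), while miR-125b, miR-26a and miR-29b had adjusted p-values of 0.0723, 0.305 and 0.542. Since 461 of 593 miRNAs differed between regions, unrelated arms would often differ in ratio too; no such pairs, and neither GC content nor the stability of the arms, were tested, so which hairpin was in use stays open.

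Averaged over both regions and times, enrichment gave 11 calls with edgeR, 10 higher and 1 lower, and 24 without library 3 of 10wEE_CA, 17 higher and 7 lower. Without that library the mean log2 fold changes were 0.39 for miR-132-3p, 0.43 for miR-212-3p, 0.33 for miR-212-5p and 0.30 for miR-132-5p. The other higher ones included miR-375-3p (0.37), miR-34c-5p (0.34, but -0.05 ± 0.20 in DG at 2 weeks), miR-381-3p (0.19), miR-21a-5p (0.19), miR-22-3p (0.14) and miR-27b-3p (0.13). Lower ones included miR-187-5p (-0.31), miR-187-3p (-0.24), miR-148a-3p (-0.20), miR-873a-3p (-0.20) and miR-551b-3p (-0.19). That the Dlk1-Dio3 cluster rises as a set was a hypothesis, and the camera p with an estimated correlation was 0.746. These averages took CA and DG libraries as independent, although some may come from the same animal.

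A hypothesis is that enrichment raises the miR-132/miR-212 transcript in both regions at both times. Only mature arms were counted, so the transcript itself was not tested. The mean log2 fold change of the 4 arms was as large in 1 of 100 splits, the real one, in each contrast: 0.52 in DG at 2 weeks (highest other 0.48), 0.31 in DG at 10 weeks (0.23), 0.31 in CA at 2 weeks (0.30) and 0.26 in CA at 10 weeks (0.22), or 0.31 without library 3 of 10wEE_CA (0.23). In each contrast the real grouping thus gave the largest mean, in CA at 2 weeks by a narrow margin. With only 100 splits, chosen after the data were seen, chance is less likely but not excluded. Whether the size differs between the 4 contrasts cannot be told apart, with a smallest adjusted p of 0.0595 in a Cochran Q test without that library, for miR-132-5p.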
